A study of Mus musculus with 8 samples.

How the data were processed

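Lungs of newborn mice were profiled on 8 Agilent microarrays hybridised with 1 dye (Cy3). Per the labels, the pups were of the C57Bl/6J background and were kept in 85% oxygen from postnatal day 0 to day 3. The labels assign 4 arrays to pups heterozygous for Fgf10 and 4 to wild-type pups, and every array is a separate sample per the series' design text. No statement ties the samples to separate litters, so p-values measure the spread between these samples. Total RNA was isolated with a column kit and amplified with Agilent's low-input kit, per the labels' protocols.

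The deposited table held log2 intensities for 62976 array features on each of the 8 arrays. The submitters' processing notes name limma, with no version or step. The means, standard deviations and quantiles of the 8 deposited log2 columns were nearly identical, which is how quantile-normalized values look, so no further normalization was applied. The background correction is not given in the sources used here, and the table holds no background level or detection call, so whether a dim feature lay above background is unknown. The brightest features sat at the top of the scale, near 15.99 on the log2 scale. There were 301 missing values in 189 features, of which 52 were named, and features with any missing value were left out. No depth exists for arrays, and their number limits the precision.

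Gene symbols came from the platform annotation. It gave 31465 features 1 symbol each, gave none several symbols and left 31511 features unnamed here. Of the named features, 29050 were matched by accession to the RefSeq gene table of assembly GRCm38.p6, and 2933 symbols were updated, which gave 20863 symbols. The build behind the array design is not given in the sources used here, so no coordinates are printed and the RefSeq table served only for names and for the order of neighbouring genes. Features of a gene cannot be sorted into repeated spots and different probes, because no probe sequences were used.

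Features whose mean over all 8 arrays lay below the 30th percentile (2.76 on the log2 scale) were removed, which left 25747 named features. The feature with the highest mean represented each gene, giving 17229 tested genes, of which 11502 had 1 feature and 5727 had several. Genes were tested in R 4.3.3 with limma 3.58.1 (lmFit, then eBayes with a variance trend over intensity), as labelled Fgf10+/- minus wild-type, two-sided. A gene was called at a Benjamini-Hochberg adjusted p below 0.05. Confidence intervals are 95% intervals from the same fit, and errors of fold changes are its standard errors (SE).

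Before the data were examined, 43 gene lists were fixed (cell types of the lung and of neighbouring tissues, signalling pathways, matrix, metabolism and stress responses), and 42 had at least 4 measured members. The list of Y-linked genes was not tested. Lists were tested with limma's camera at its preset correlation between genes of 0.01, with Benjamini-Hochberg adjustment over the 42 lists, and again with the correlation estimated from the data. A list score is the mean over the members of each array's log2 value minus that gene's mean over the 8 arrays. Scores and the Fgf10 values were compared by two-sided exact permutation tests over the 70 assignments of 4 against 4 arrays, for which the smallest possible p is 0.0286. limma's fry was used as an alternative, and its mixed test, which asks whether members of a list change in either direction, was used for the genes flanking Fgf10.

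The genes named in the text were set by a rule fixed before the data were examined. It takes Fgf10, then the 10 higher and 10 lower called genes with the largest fold change whose groups do not overlap, leaving out predicted genes. It adds up to 4 members with the smallest unadjusted p from each called list and from 9 lists on the FGF10 pathway, alveolar cells, fibroblasts, endothelium, elastic fibre, oxidative stress and the Fgf10 neighbours, and a panel of 25 genes. Genes named outside this rule are said to be chosen after their values were seen.

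The gene and list tests were tested on simulated data in 10 runs of the same 4 against 4 comparison. In each run 200 of 17229 genes were changed at random, and all measured cell cycle genes were lowered by 0.5 besides. Among the 200, the fit recovered 18.0% of genes changed by 0.5 and 52.9% of genes changed by 1 on the log2 scale. Of all its calls, 3.10% were on genes changed in neither way. The cell cycle list was called in 10 of 10 runs, and no other list was called. Simulated genes varied independently of each other, while the correlation estimated from the data was 0.51 for the cell cycle list. The runs therefore do not show how often lists or genes are falsely called where genes are correlated. The alternatives were other normalizations, filters and thresholds, other ways to combine features, a fit without the variance trend, a test of each gene on its own variance, array weights, the Xist level as a covariate, the replicate number as a block, and each array left out in turn. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.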

Results

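The series compared whole lungs of newborn mice labelled as heterozygous for Fgf10 with lungs labelled wild-type, after both had been kept in 85% oxygen from postnatal day 0 to day 3. High oxygen in the newborn mouse disturbs alveolar development and is used as a model of bronchopulmonary dysplasia. Fgf10 is a growth factor made by the lung mesenchyme that acts on epithelium through the receptor Fgfr2b. There were 4 arrays per group and no arrays from pups kept in room air, so the values describe a genotype difference under oxygen only. Pearson correlations between arrays of 1 group lay between 0.975 and 0.985 and those across groups between 0.974 and 0.987.

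Fgf10 itself was not lower in the arrays labelled Fgf10+/-. Its brightest feature read 8.04 ± 0.20 in them and 7.81 ± 0.28 in wild-type arrays (log2 intensity, mean ± SD, n = 4 each), a difference of 0.23 with an exact permutation p = 0.2. All 10 Fgf10 features had a higher mean in the arrays labelled Fgf10+/-, by 0.06 to 0.44. Their mean was 7.65 ± 0.20 against 7.42 ± 0.25 (SD, n = 4 each, exact permutation p = 0.229). Neither the deleted part of the gene nor the position of the features is given in the sources used here, so Fgf10 does not check the labels. The sample titles name this group TG, while its genotype label reads heterozygous, and nothing in the sources used here says what TG stands for. Every direction below therefore rests on the labels alone.

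In the lungs labelled Fgf10+/-, genes of cell division and extracellular matrix were lower and genes of alveolar type 2 cells were higher. Macrophage genes were lower too, with a median of -0.53 that was -0.23 without wild-type array 1. These were among 13 gene lists called by limma's camera at its preset correlation. None of the 13 passed with an estimated correlation, where the smallest adjusted p was 0.165. As many lists were called in 6 of the 35 splits of the arrays into 4 and 4, the real one included. Of 17229 genes, 137 were called by limma, 39 higher and 98 lower. A change of at least 2-fold was seen in 4 of the higher and 41 of the lower genes. In 136 of the 137 called genes the 4 arrays of a group lay apart from the 4 of the other, the exception being Phlda3. Among all genes 6.64% were apart in this way, against 2.86% by chance. The calling rule itself favours genes whose groups lie apart, so the 136 are no separate support for the calls. The count fell to 34 without wild-type array 2 and to 1 without the variance trend.

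The largest rise among genes taken by the rule was in Vmn1r197, a vomeronasal receptor gene, at a log2 fold change of 2.38 (95% CI 1.54 to 3.23, limma adjusted p = 0.014). Its mean was 5.54 in arrays labelled Fgf10+/- and 3.16 in wild-type arrays, the latter near the filter level of 2.76. Whether its wild-type values lay above background is unknown. Kiss1, which encodes the precursor of kisspeptin, rose by 2.10 (SE 0.23, limma adjusted p = 0.00341). Cyp2e1, a cytochrome P450 of xenobiotic metabolism, rose by 1.82 (SE 0.33), although its other feature had the opposite sign. Pcdhb18 rose by 1.18, the mitochondrial adenylate kinase Ak4 by 0.97 and Bex2 by 0.91. The transcription factor Tfcp2l1 rose by 0.86, the alanine transaminase Gpt by 0.81, the secreted WNT inhibitor Wif1 by 0.77 and the cardiac and slow muscle myosin Myh7 by 0.76. Standard errors of these 7 genes lay between 0.12 and 0.25. With each of the 8 arrays left out in turn, Pcdhb18 kept its call in 0 runs, Ak4 in 1 and Wif1 in 2.

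Among the lower genes, Ckap2, a protein of the mitotic spindle, was 4.63-fold lower (log2 fold change -2.21, 95% CI -2.88 to -1.54, limma adjusted p = 0.00729). The mitotic kinesin Kif18b changed by -2.19 (SE 0.38), Lrtm2 by -2.07 (SE 0.33) and Spp1, which encodes osteopontin, by -2.06 (SE 0.40). In arrays labelled Fgf10+/- the mean of Lrtm2 was 2.31, below the filter level of 2.76, and that of Kif18b was 3.02, near it. Whether these values of Lrtm2 and Kif18b lay above background is unknown. Tfr2, a transferrin receptor, changed by -1.93 (SE 0.36). In arrays 1, 3 and 4 labelled Fgf10+/- Tfr2 read 3.41, 3.21 and 3.25, and whether these values lay above background is unknown. The remaining 5 of the 10 act in cell division. Pimreg changed by -1.74, the DNA topoisomerase Top2a by -1.73, Cdkn3 by -1.72, Aspm by -1.72 and Prc1 by -1.70, with limma adjusted p between 0.00508 and 0.0463. Spp1, Top2a and Aspm each kept their call in 2 of the 8 runs with 1 array left out, and Tfr2 in 3.

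**Figure D1:**
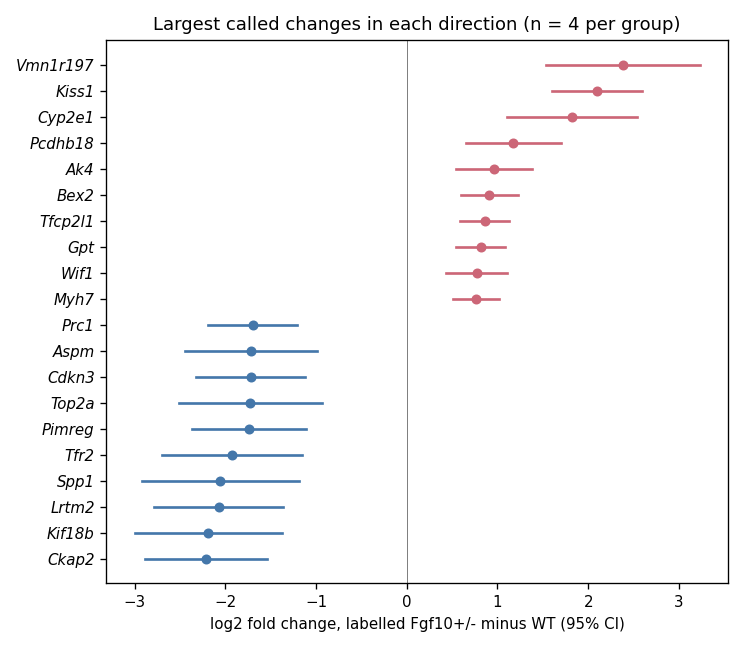
Log2 fold change (horizontal axis, arrays labelled Fgf10+/- minus wild-type, n = 4 each) of the 10 higher (red) and 10 lower (blue) genes of the naming rule. Points are limma estimates and lines 95% confidence intervals, and the estimates run from -2.21 for Ckap2 to 2.38 for Vmn1r197.

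Of the 42 gene lists tested, limma's camera called 13, of which 4 were higher and 9 lower. None of them passed with the correlation between genes estimated from the data, where 7 lists had an unadjusted p below 0.05. By exact permutation of the list scores 8 lists reached the smallest possible p of 0.0286, and none passed adjustment, the smallest adjusted p being 0.15. With 4 arrays per group no list could pass adjustment over 42 lists unless many others reached that smallest p with it. The lack of passing lists in the permutation test therefore does not count against any of them.

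Genes of the cell cycle fell furthest as a group. Of 27 measured members 13 were called lower, 14 did not pass, and 17 were lower when adjusted over the list alone. The median log2 fold change was -1.01 and all 27 members had a negative sign (camera adjusted p = 1.92e-24, adjusted p = 0.165 with an estimated correlation). Cyclin B2 (Ccnb2) changed by -1.48 (SE 0.18), the spindle assembly factor Tpx2 by -1.58 (SE 0.22), the survivin gene Birc5 by -1.42 (SE 0.22) and Cdc20, an activator of the anaphase-promoting complex, by -1.32 (SE 0.21). The members that did not pass included the replication genes Pcna at -0.12 (SE 0.11) and Mcm2 at -0.13 (SE 0.18), both chosen after their values were seen. List scores were -0.46 ± 0.24 in arrays labelled Fgf10+/- and 0.46 ± 0.36 in wild-type arrays (SD, n = 4 each, exact permutation p = 0.0286), and wild-type array 1 had the lowest wild-type score, -0.058.

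Markers of alveolar type 2 cells, which make surfactant, rose. Of 14 members 5 were called higher and 9 were not, and 7 were higher when adjusted over the list alone (median 0.39, camera adjusted p = 1.02e-08, adjusted p = 0.165 with an estimated correlation). The phosphate transporter Slc34a2 rose by 0.72 (SE 0.11), the surfactant lipid transporter Abca3 by 0.48 (SE 0.08), the lamellar body protein Lamp3 by 0.51 (SE 0.09) and Lpcat1, which makes surfactant phosphatidylcholine, by 0.58 (SE 0.12). Slc34a2 kept its call in all 8 runs with 1 array left out, Abca3 in 5, Lamp3 in 4 and Lpcat1 in 2. The surfactant protein genes did not pass, with Sftpb at 0.14 (SE 0.09), Sftpa1 at 0.10 (SE 0.09) and Sftpc at 0.00 (SE 0.06), the last of which lay near the top of the scale. The lung epithelial transcription factor Nkx2-1 had a value of 0.41 (SE 0.09, limma adjusted p = 0.0691). In the list of fatty acid and surfactant lipid synthesis, which shares Lpcat1, all 14 members had a positive sign. Lpcat1 was called and 13 members were not, and 4 were higher when adjusted over the list alone (median 0.18, camera adjusted p = 3.65e-05, adjusted p = 0.165 with an estimated correlation). Scd1, a fatty acid desaturase, had a value of 0.44 (SE 0.11), the fatty acid binding protein Fabp5 0.42 (SE 0.11) and Acly 0.22 (SE 0.08).

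Other epithelial groups were less clear. Markers of ciliated cells were higher as a list (median 0.35, camera adjusted p = 3.10e-05, adjusted p = 0.431 with an estimated correlation), but none of 15 members passed, including when adjusted over the list alone. Their values were 0.52 for Dnah5, 0.35 for Tppp3, 0.55 for Fam183b and 0.72 for Sntn. Wild-type array 4 had the lowest ciliated score, -0.65, and the median was 0.23 without it. None of 13 markers of alveolar type 1 cells, the flat cells of gas exchange, was called, and the list had a median of -0.06 (camera adjusted p = 0.352). Its values included -0.14 (SE 0.10) for Ager, -0.06 (SE 0.10) for Hopx and -0.09 (SE 0.10) for Pdpn. The club cell gene Scgb1a1 differed by 0.01 (SE 0.06) at the top of the scale, and none of 10 club and secretory cell markers was called (median 0.16, camera adjusted p = 0.0886).

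In the FGF10 pathway, Etv5, a transcription factor downstream of FGF receptors, rose by 0.41 (SE 0.07, limma adjusted p = 0.0203), and the ligand gene Fgf9 was lower at -1.29 (SE 0.25, adjusted p = 0.027). Etv5 kept its call in 4 and Fgf9 in 2 of the 8 runs with 1 array left out. The other 14 of 16 members did not pass, and camera did not call the list (median 0.08, camera adjusted p = 0.572). The list did pass limma's mixed fry test, which takes changes in either direction (adjusted p = 0.00129), as 15 of the 42 lists did. Adjusted over the list alone, the same counts of 1 higher and 1 lower were found. Fgfr1 had a value of -0.34 (SE 0.13), Spry1 0.22 (SE 0.12), Fgfr2 0.23 (SE 0.14) and Spry2 0.38 (SE 0.33). Among WNT targets Wif1 was called and 11 members were not (camera adjusted p = 0.185). None of 7 hedgehog members (camera adjusted p = 0.187) and none of 10 BMP members (adjusted p = 0.888) was called, with Shh at 0.00 (SE 0.17) and Bmp4 at -0.46 (SE 0.12).

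Genes of the extracellular matrix were lower. In the elastic fibre list Loxl2, a lysyl oxidase that cross-links collagen and elastin, was called lower at -0.87 (SE 0.13, limma adjusted p = 0.01). The other 14 of its 15 members did not pass, and 7 were lower when adjusted over the list alone (median -0.30, camera adjusted p = 7.78e-07, adjusted p = 0.184 with an estimated correlation). Ltbp2 had a value of -0.43, Loxl1 -0.30 and Mfap5 -0.58, while elastin itself (Eln) had -0.29 (SE 0.24), which ranged from -0.53 without array 3 labelled Fgf10+/- to -0.066 without wild-type array 3. Collagens were lower as a list (median -0.24, camera adjusted p = 4.02e-05, adjusted p = 0.421 with an estimated correlation). None of their 12 members passed, and 4 were lower when adjusted over the list alone, namely Col4a1 at -0.39, Col14a1 at -0.38, Col12a1 at -0.53 and Col4a2 at -0.25. The other feature of Col14a1 had the opposite sign. Wild-type array 1 had scores of -0.045 for elastic fibre and -0.24 for collagens, below the other 3 wild-type arrays.

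TGF-beta targets were lower as a list (median -0.28, camera adjusted p = 0.000162, adjusted p = 0.165 with an estimated correlation). None of 12 members passed, and 4 were lower when adjusted over the list alone, namely thrombospondin 1 (Thbs1) at -0.48, Ltbp2, fibronectin (Fn1) at -0.35 and Tgfb2 at -0.38. Smooth muscle genes gave a similar result (median -0.24, camera adjusted p = 0.000436, adjusted p = 0.34 with an estimated correlation), with none of 11 members called and 3 lower when adjusted over the list alone. The smooth muscle median was -0.16 without wild-type array 2. Calponin (Cnn1) had a value of -0.34, Myocd -0.63, Acta2 -0.30 and Myh11 -0.32.

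Neither list of fibroblast markers passed, and their difference from the matrix lists was not tested. None of 13 lipofibroblast and matrix fibroblast markers was called, and the median of 0.01 and mean of -0.01 differed in sign (camera adjusted p = 0.618). Slc7a10 had a value of 0.68 (SE 0.20), Limch1 -0.22 (SE 0.11), Fabp4 -0.43 (SE 0.21), Macf1 -0.17 (SE 0.09) and the lipid droplet gene Plin2 -0.22 (SE 0.15). Among 11 alveolar myofibroblast markers the autotaxin gene Enpp2 rose by 0.55 (SE 0.10, limma adjusted p = 0.0192) and 10 did not pass (median 0.02, mean -0.02, camera adjusted p = 0.887). Adjusted over the list alone, 1 was higher and 2 were lower. Enpp2 kept its call in 4 of the 8 runs with 1 array left out. Aspn had a value of -0.34, P2ry14 -0.38, Mustn1 -0.46 and Pdgfra 0.12. With each array left out in turn, the medians ranged from -0.17 to 0.07 for lipofibroblast and matrix fibroblast markers, lowest without array 2 labelled Fgf10+/-, and from -0.19 to 0.09 for alveolar myofibroblast markers, lowest without array 4 of that group.

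**Figure D2:**
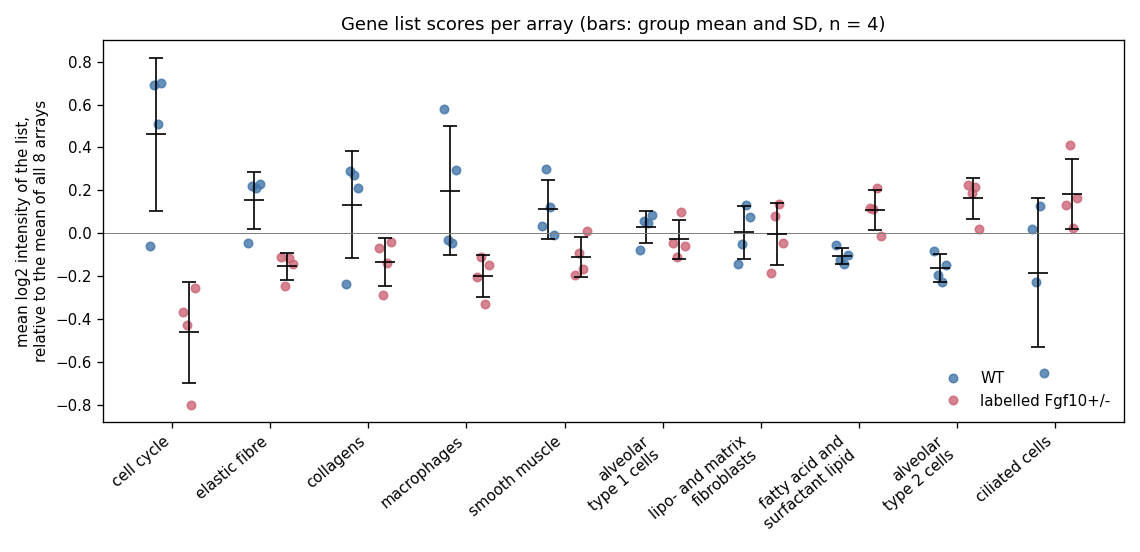
Score of 10 gene lists (vertical axis, mean log2 intensity of the members relative to the mean of all 8 arrays) for each wild-type (blue) and labelled Fgf10+/- (red) array, with group mean and SD (n = 4). Cell cycle scores were -0.46 ± 0.24 in the labelled Fgf10+/- group and 0.46 ± 0.36 in the wild-type group, and alveolar type 2 scores 0.16 ± 0.10 and -0.16 ± 0.06.

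Macrophage genes were lower as a list (median -0.53, camera adjusted p = 0.00107, adjusted p = 0.34 with an estimated correlation). Spp1 was called and 14 of 15 members were not. Adjusted over the list alone 5 were lower and 1 higher, with the complement genes C1qb at -0.88, C1qc at -0.59 and C1qa at -0.61. The score was highest in wild-type array 1, at 0.58, and the median was -0.23 without that array, -0.34 without array 3 and -0.29 without array 4 labelled Fgf10+/-. Wild-type array 1 also had the highest scores of the 8 arrays for inflammatory cytokines, 1.63 against -0.46 to -0.20 in the other wild-type arrays, and for neutrophils, 0.61. Targets of p53, the DNA damage response factor, were lower (median -0.22, camera adjusted p = 0.00823, adjusted p = 0.165 with an estimated correlation), with Phlda3 called at -0.63 (SE 0.13) and 10 members not called. Adjusted over the list alone 4 were lower and 1 higher, Cdkn1a having a value of -0.45, Zmat3 -0.48 and Bbc3 0.39. Phlda3 kept its call in 3 of the 8 runs with 1 array left out. The p53 target Cdkn1a, an inhibitor of the cell cycle, missed the threshold with a limma adjusted p = 0.0506.

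Immediate early genes, which respond within minutes to stimulation and to tissue handling, were higher as a list (median 0.26, camera adjusted p = 0.0052, adjusted p = 0.431 with an estimated correlation). None of 14 members passed, and 2 were higher when adjusted over the list alone, Nr4a1 at 0.59 (SE 0.14) and Egr1 at 0.95 (SE 0.29), with Junb at 0.71 and Jun at 0.19. Array 3 labelled Fgf10+/- scored 0.38 and wild-type array 1 scored 0.30, and the median was 0.41 without the latter. With both arrays left out, a choice made after seeing the data, 110 genes were called, 24 higher and 86 lower.

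Among vessels, the lymphatic list was lower (median -0.37, camera adjusted p = 0.011, adjusted p = 0.257 with an estimated correlation). Mmrn1 was its 1 called member at -0.67 (SE 0.12), also when adjusted over the list alone, and 4 did not pass, with Prox1 at -0.95, Lyve1 at -0.37 and Flt4 at -0.32. Mmrn1 kept its call in 4 of the 8 runs with 1 array left out. With arrays labelled Fgf10+/- left out, Prox1 had -0.61 without array 1, and Lyve1 had -0.20 without array 2 and -0.55, which was then the lymphatic median, without array 3. None of 20 markers of blood vessel endothelium was called (median -0.04, camera adjusted p = 0.185), with Plvap at -0.27, Eng at -0.24, Flt1 at -0.27 and Aplnr at 0.47. That list was called lower in 2 of the 8 runs with 1 array left out, with a median of -0.12 without wild-type array 1 and -0.049 without array 3 labelled Fgf10+/-. Pecam1 had a value of -0.29 (SE 0.15), Kdr -0.04 (SE 0.10) and the angiogenic factor Vegfa -0.15 (SE 0.08). Mesothelial genes were lower as a list (median -0.58, camera adjusted p = 0.0206, adjusted p = 0.488 with an estimated correlation), with none of 9 called and 1 lower when adjusted over the list alone. Their values were -0.66 for Msln, -1.19 for Wt1, -1.15 for Upk3b and -0.58 for Bnc1. Wild-type array 4 had a mesothelial score of 1.35, and without it the median was -0.15, no longer called, with Msln at -0.44, Wt1 at -0.49 and Upk3b at -0.46.

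The antioxidant targets of NRF2, which respond to oxygen stress, did not differ detectably. None of 16 members was called, also when adjusted over the list alone (median 0.05, camera adjusted p = 0.574), and Nqo1 had a value of 0.14 (SE 0.24). The list median was -0.038 without wild-type array 2 and -0.021 without wild-type array 4, and Nqo1 ranged from -0.052 without wild-type array 2 to 0.32 without wild-type array 1. Me1 had 0.15, Gclc 0.17, Gsta3 0.14 and Cbr3 -0.21. Pericytes had 1 lower gene, Postn at -0.48 (SE 0.09, named after its value was seen, camera adjusted p = 0.201 for the list), and cardiac muscle 1 higher, Myh7 (camera adjusted p = 0.514). No member was called and no list passed for B cells (camera adjusted p = 0.0763), cholesterol synthesis (0.0875), interferon response (0.0886), inflammatory cytokines (0.173), mast cells and basophils (0.173) and hypoxia response (0.185). The same held for erythroid cells (0.352), adipocytes (0.415), circadian clock (0.775), thymocytes, T and NK cells and skeletal muscle (each 0.856), neuroendocrine cells (0.888), neutrophils (0.935), stratified epithelium (0.946) and glucocorticoid targets (0.967). Adjusted over the list alone, 4 WNT targets and 1 interferon gene were higher, 2 hypoxia genes were lower, 2 BMP targets were higher and 1 was lower, and the counts of pericytes (1 lower) and cardiac muscle (1 higher) stayed as they were.

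Genes next to Fgf10 on its chromosome changed in both directions. Among 17 measured genes of the list fixed for this region, 4833420G17Rik rose by 0.70 (SE 0.09, limma adjusted p = 0.00377), while Fst, which encodes the activin antagonist follistatin, was lower at -1.04 (SE 0.19, adjusted p = 0.0217) and Paip1, a partner of the poly(A) binding protein, at -0.79 (SE 0.16, adjusted p = 0.0425). The other feature of Paip1 had the opposite sign. With each of the 8 arrays left out in turn, Paip1 kept its call in 1 run, Fst in 3 and 4833420G17Rik in 8. The other 14 genes did not pass, and adjusted over the list alone 1 was higher and 3 were lower. Nnt, a mitochondrial transhydrogenase gene beside Fgf10, had a value of -0.40 (SE 0.13). The list had no common direction (median -0.03, camera adjusted p = 0.888), and limma's mixed fry test, which takes changes in either direction, gave an adjusted p = 1.18e-06. That test passed for 15 of the 42 lists, among them the FGF10 pathway, WNT targets and alveolar myofibroblasts, which camera did not call.

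**Figure D3:**
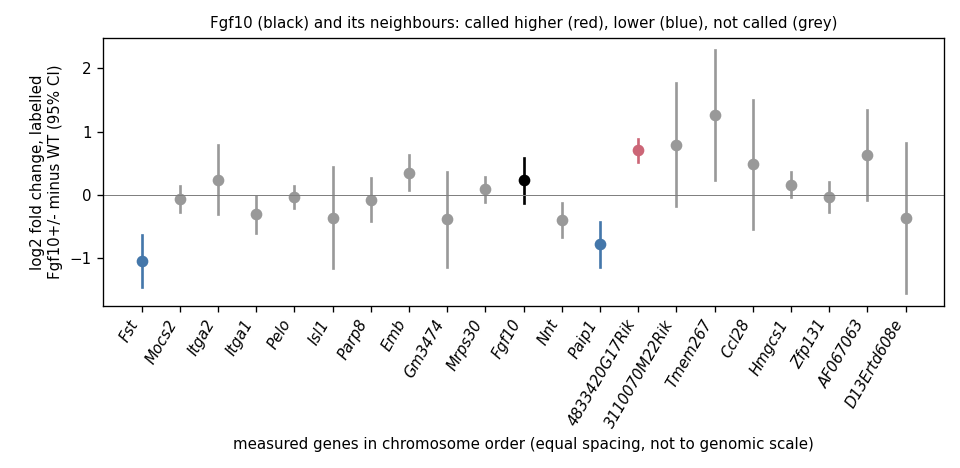
Log2 fold change (vertical axis, arrays labelled Fgf10+/- minus wild-type, 95% CI, n = 4 each) of Fgf10 (black) and the 10 nearest measured genes on each side, in RefSeq order and equally spaced, not to genomic scale. Red marks a called rise (4833420G17Rik, 0.70), blue a called fall (Fst, -1.04, and Paip1, -0.79) and grey genes that did not pass.

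The sex of the pups is not given in the labels. Xist, the RNA of the inactive X chromosome, was low in arrays 2 and 3 labelled Fgf10+/- (2.63 and 1.93) and in wild-type array 3 (2.01), and lay between 6.29 and 6.85 in the other 5 arrays. The Y-linked gene Eif2s3y was high in the same 3 arrays, between 10.1 and 10.3. Uty, the other measured Y-linked gene, was dim and did not follow this split, with 4.61 in array 1 labelled Fgf10+/- and 2.74 in wild-type array 3. Both Y-linked genes were named after their values were seen. With the Xist level as a covariate 80 genes were called, 21 higher and 59 lower.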

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

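The tests of fibroblast and type 1 markers, of mislabelled arrays and of the deleted part of Fgf10 were chosen after the result was seen, as was setting the Xist covariate, a run fixed before the data were examined, against the sex of the pups. Of 318 sets of 4 values examined, 22 held an array far from the other 3 of its group, where 15.9 would be expected by chance.

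Wild-type array 1 had list scores far from the other wild-type arrays for inflammatory cytokines (1.63, others -0.46 to -0.20), elastic fibre (-0.045), collagens (-0.24) and immediate early genes (0.30), and the lowest wild-type values of Kif18b (4.35) and Birc5 (10.28). Array 3 labelled Fgf10+/- stood apart in its immediate early gene score (0.38), in Vmn1r197 (6.41, above the others) and in Top2a (4.50, below the others). Array 4 labelled Fgf10+/- was below the others of its group in Tfcp2l1 (8.77), Lamp3 (13.34), Limch1 (12.98) and, by a very small margin at the top of the scale, Scgb1a1 (15.95), and above them in the pericyte score (0.098). Array 2 labelled Fgf10+/- was high in Tfr2 (4.79) and low in the mesothelial gene Wt1 (3.08), and array 1 of that group was high in Kdr (12.38) and low in the neuroendocrine score (-0.22). Wild-type array 2 was low in Aqp5 (12.61). Wild-type array 4 was high in Sftpb (15.06) and low in Hopx (13.33). Xist was low in wild-type array 3 (2.01), the only array of its group with a high Eif2s3y value.

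Lower cell-cycle genes were weighed against 3 explanations. The first was the authors' normalization shifting genes of this brightness. Among 10000 random lists matched on mean level the lowest median was -0.16, far above the observed -1.01. Near-identical columns keep median changes small at every brightness (-0.013, 0.015 and 0.009 in the dimmest, middle and brightest 5743 genes). Lists matched on level could thus hardly come near -1.01, and the comparison does not decide on the normalization. With the Xist level as a covariate the median was -0.97, which argues against unequal numbers of males and females. Markers of lipofibroblasts and alveolar myofibroblasts had a median of 0.013 (SD 0.30 over 24 markers), which argues against a smaller share of these fibroblasts as the whole cause. The collagen, elastic fibre and smooth muscle lists had medians of -0.24, -0.30 and -0.24, so a smaller share as a part of the cause stays open. Fewer dividing cells in the lungs labelled Fgf10+/- may account for the pattern, as a hypothesis, and whole-lung arrays leave open which cells those would be.

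Higher alveolar type 2 markers were weighed against 2 explanations. With the Xist level as a covariate their median was 0.38 against 0.39 without it, which argues against the sex of the pups. A smaller share of non-epithelial cells would raise all epithelial markers alike, but type 1 markers had a median of -0.057 (SD 0.20 over the markers). Ciliated markers (median 0.35) and club and secretory markers (median 0.16) had the sign of the type 2 markers, so the argument rests on the type 1 markers. Smooth muscle (median -0.24), macrophages (-0.53), lymphatic endothelium (-0.37) and mesothelium (-0.58) were called lower. Other non-epithelial lists, among them both fibroblast lists and blood vessel endothelium, were not called. A smaller share of some non-epithelial cells as a part of the cause stays open. A larger share of type 2 cells, or more RNA of these genes per cell, may account for the pattern, and the arrays do not separate these.

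Neighbours of Fgf10 changed while Fgf10 was not lower. The 20 nearest measured genes had a mean absolute limma statistic of 2.11, against a median of 1.06, at percentile 99.96 of 16581 windows of 20 genes, and 7 of the 20 had an unadjusted p below 0.05 (median window 2), which is consistent with DNA of another strain linked to the targeted allele. In the fit with the variance trend, the other 34 splits and the 8 relabellings of 1 array gave at most 57 called genes (wild-type array 1 relabelled) against 137. This argues against mislabelled or swapped single arrays in that fit only. Without the trend the real split gave 1 gene and the highest other split 3, and the relabellings were not run. An exchange of both whole groups would leave all these counts as they are and stays open. Whether the Fgf10 features lie outside the deleted part cannot be told, as 0 of 10 features had a lower mean and no probe positions were used. C57BL/6J mice are known to carry a deletion within Nnt, but without probe positions the 3 Nnt features do not show which Nnt allele was present. The feature at -0.40 was bright (10.06 in arrays labelled Fgf10+/-, 10.46 in wild-type arrays). Those at 0.82 (4.52 and 3.70) and -0.65 (2.56 and 3.22) were dim, so their signs carry little weight.

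The count of called genes was set against all 35 splits of the 8 arrays into 4 and 4. In the fit with the variance trend only 1 split, the real one, gave as many as 137 genes, and the highest of the others gave 24. This argues against chance for this count in that fit. The share of 0.0286 is the smallest that 35 splits can give, so chance is not excluded. Without the trend the real split gave 1 gene and the highest other split 3, so the count did not stand out there. The split with 24 genes set array 1 labelled Fgf10+/- with wild-type arrays 1, 2 and 4 against the rest, which are 4 of the 5 arrays with high Xist. For the 13 called lists, 6 of the 35 splits gave as many and the highest other split gave 20, so chance is not excluded for the number of lists.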

How the results depend on the processing

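The run without both arrays of high immediate early genes was chosen after the data were seen, and the other alternatives were planned. No called value of a named gene or list changed sign where 1 value per gene was refitted, but with features taken alone the other features of Cyp2e1 and Paip1 had the opposite sign. Without the variance trend 1 gene was called (0 higher, 1 lower), and with each gene tested on its own variance also 1 (1 higher, 0 lower). Median residual SD was 0.55, 0.24 and 0.14 in the dimmest, middle and brightest 5743 genes, where 6, 49 and 82 genes were called. In simulated data the fit without the trend recovered 5.4% of genes changed by 0.5 and 45.4% of those changed by 1 on the log2 scale. The simulated changes were placed at random over genes of every brightness, unlike the real calls. The simulation therefore does not decide on the loss of nearly all calls. The Xist covariate gave 80 genes (21 higher, 59 lower), of which 78 were among the 137. The threshold moved the count to 278 (98 higher, 180 lower) at an adjusted p below 0.1, to 1926 (929 higher, 997 lower) at an unadjusted p below 0.05, where 861 are expected, and to 91 (20 higher, 71 lower) with at least 1.5-fold change. Leaving out each array in turn gave 34 genes (wild-type array 2) to 177 (wild-type array 1), 15 to 54 higher, 19 to 130 lower, and 13 to 18 lists. It gave 69, 83, 63 and 59 genes without arrays 1 to 4 labelled Fgf10+/-, and 62 without wild-type array 4. Without both arrays of high immediate early genes 110 genes (24 higher, 86 lower) and 21 lists were called, 79 of the genes being among the 137.

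Between 108 and 162 genes were called with array weights, other filters or the mean of all features, and 179 of 43928 features were called with every feature tested alone, 24 of them unnamed. Quantile normalization again and equal 75th percentiles left the 137 as they were, but moved almost nothing, since the deposited values were already normalized, and so test nothing. With an estimated correlation camera called 0 lists, against 7 at an unadjusted p below 0.05 and 5 with fry (cell cycle, type 2 cells, lipid synthesis, TGF-beta and p53 targets). Of 37 named genes that were called, 36 lost the call without the variance trend, 22 without wild-type array 2, 17 without wild-type array 4, 17, 16, 14 and 11 without arrays 4, 2, 3 and 1 labelled Fgf10+/-, 11 with the Xist covariate, and 8 and 3 without wild-type arrays 3 and 1. Of 18 alternatives the call was lost in 13 for Pcdhb18 and Paip1, in 11 for Ak4 and Lpcat1 and in 10 for Phlda3 and Top2a. The mesothelial list lost its call in 7 of 20 alternatives, and its median was -0.15 without wild-type array 4. Fgf10 features 21322 and 34412, with the largest differences of the 10, gave 0.43 and 0.44 with an unadjusted limma p below 0.05. By exact permutation their p were 0.0571 and 0.114. The main Fgf10 difference ranged from 0.14 to 0.35 with arrays left out. Where no cause is named above, the cause was not tested.

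Groups share replicate numbers 1 to 4 in the labels, but the numbers did not pair the arrays. Deviations of same-numbered arrays correlated at -0.0046, -0.064, 0.028 and 0.067, and 1 of 4 arrays labelled Fgf10+/- and 2 of 4 wild-type arrays were closest to their own number. With the replicate number as a block 116 genes (35 higher, 81 lower) and 13 lists were called, 100 of the genes being among the 137. Signal over background is unknown, which limits what dim genes can show.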

Other observations

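The genes in this part were chosen after their values were seen, with no further test than limma's adjusted p. The lower genes named here, from outside the fixed lists, each had the 4 arrays labelled Fgf10+/- below all 4 wild-type arrays, and no grouping of them was tested. Sod3, the extracellular superoxide dismutase, shared the smallest adjusted p of all genes with Kiss1 (log2 fold change -0.93, SE 0.10, limma adjusted p = 0.00341). The proteoglycan Bgn (biglycan) changed by -1.18, the gelatinase Mmp2 by -0.71, the aggrecanase Adamts4 by -0.90, Adamts2 by -0.57, Thbs2 by -0.87 and Ecm1 by -0.61. The growth factor Igf1 changed by -0.80 (SE 0.13, limma adjusted p = 0.0134), the EGF receptor ligand Ereg by -1.68 (SE 0.33) and the plasminogen activator Plat by -0.84. The complement inhibitor Serping1 changed by -0.58, Hsd11b1, which regenerates active glucocorticoid, by -0.74, and the iron exporter Slc40a1 by -0.60, beside the transferrin receptor Tfr2. Cyclin D1 (Ccnd1), which acts earlier in the cycle than the mitotic genes, changed by -0.42 (SE 0.07).

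Higher genes from outside the fixed lists are likewise single calls. The transcription factor Elf5 rose by 0.67 (SE 0.10, limma adjusted p = 0.01), Lgi3 by 0.68 (SE 0.08), the tight junction gene Cldn3 by 0.50, the membrane linker Ezr by 0.42 and the phospholipase Pla2g1b by 0.69. Rbpjl rose by 0.56 and the acyl-CoA thioesterase Acot1 by 0.51. Among features with no gene name here, 18181 were tested and 24 were called, 14 higher and 10 lower.

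Wild-type array 4 had scores of 1.35 for mesothelium, 0.72 for cardiac muscle and 0.79 for stratified epithelium, each the highest of the 8 arrays.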
